A study of Mus musculus with 10 samples.

How the data were processed

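Whole mouse aortas, 5 labelled Bcl11b WT and 5 labelled Bcl11b KO, were sequenced. Per the labels' protocols, total RNA was depleted of ribosomal RNA, converted to double-stranded cDNA without strand marking, tagmented and sequenced on an Illumina NextSeq instrument. The authors deposited 1 table of raw counts per gene and sample. The submitters' processing notes name HISAT2, featureCounts, DESeq2 and the mouse build mm10, without versions, roles or settings. The gene annotation and the treatment of multi-mapping reads are not given in the sources used here, so reads of paralogs such as ribosomal protein genes, and of genes overlapping on opposite strands, could have been split or lost. The table held 24449 rows, of which 25 were named only by a number, at most 0.182% of any library. Mitochondrially encoded genes were not analysed here. For coordinates, 96.2% of rows matched a symbol in GENCODE M21 on GRCm38.

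Every pair of libraries was compared by a chi-square test over genes. WT replicates 2 and 3 gave a chi-square per degree of freedom of 0.769, so their counts were summed and used as 1 library. The design fixed before the data were examined had all 10 samples, and the fit of 10 columns is reported as an alternative. Total counts per library then ran from 10156566 to 39351775, and a count of 3 corresponds to 0.0762 to 0.295 CPM of the total counts, or 0.0852 to 0.293 CPM after TMM normalization. Intervals cover the spread between libraries, and counting limits cover counting error only.

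Counts were analysed in R 4.3.3. Normalisation factors came from TMM in edgeR 4.0.16, genes were kept by filterByExpr with a minimum count of 10, and 15413 were tested with the quasi-likelihood F test, with Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 11.4%, and the median standard error of a log2 fold change was 0.104. CPM values are normalised by these factors, and log2 CPM uses a prior count of 2. The 47 gene lists fixed in advance were tested with camera in limma 3.58.1 at a preset correlation of 0.01, for the 45 lists with at least 3 tested members, with an estimated correlation and fry beside it. Group differences of single values were tested by exact two-sided permutation over the 126 splits of 9 libraries, where the smallest possible p is 0.00794. The method was tested on simulated data, with each gene drawn independently, in which a seeded set of genes was changed by known fold changes.

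Named genes followed a rule fixed before the data were examined. It took Bcl11b, up to 15 genes per direction past the threshold, otherwise up to 5 per direction with the smallest p at a mean of at least 1 CPM in the higher group, and leading members of each list. Alternatives were DESeq2 1.42.0, limma-voom, other normalisations and filters, a replicate block, sva 3.50.0, tissue-marker covariates, other thresholds and leaving out each replicate. Alternatives chosen after seeing the data were the 10 columns as separate libraries, a second replicate block, leaving out WT 2-3 and KO replicate 3, and covariates for mesothelial markers and Arntl.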

Results

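RNA was measured in whole mouse aortas by ribosomal RNA-depleted, non-directional sequencing. The labels put 5 aortas in a Bcl11b wild-type group (WT) and 5 in a group lacking Bcl11b in vascular smooth muscle (KO). Bcl11b encodes a zinc finger transcription factor best known from T cell development. The deposited table held raw counts for 24449 genes, and total counts ran from 10156566 in WT replicate 4 to 29115271 in WT replicate 2. WT replicates 2 and 3 differed by less than the sampling noise, with a chi-square per degree of freedom of 0.769 over 15351 genes, whereas the other pairs gave 3.29 to 62.2. They were therefore counted as 1 sample, called WT 2-3, with 39351775 counts, which left 4 WT and 5 KO libraries. The labels do not say whether each library came from a separate animal, so p-values measure the spread between these libraries, which may be partly technical.

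The targeted gene was looked at first in every sample. Bcl11b lies on chromosome 12 from 107910403 to 108003602 on the minus strand (GRCm38). Its counts were 14, 10, 1, 7 and 11 in WT replicates 1 to 5 and 9, 6, 6, 14 and 14 in KO replicates 1 to 5. The normalised level was 0.648 ± 0.244 CPM (counts normalised to library size; SD, n = 4) in WT and 0.709 ± 0.330 CPM (SD, n = 5) in KO, and the difference was smaller than the spread between libraries (exact permutation test, two-sided, p = 0.841). The edgeR log2 fold change was 0.21, with a 95% interval from -0.65 to 1.08, and it turned to -0.13 without WT 2-3 and -0.04 without KO replicate 4. A lower Bcl11b level in the KO group was not detectable at this depth. The labels do not give the removed exons and the aorta holds other cell types, so these counts do not check the labels, and directions below refer to libraries labelled KO and labelled WT.

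**Figure D1:**
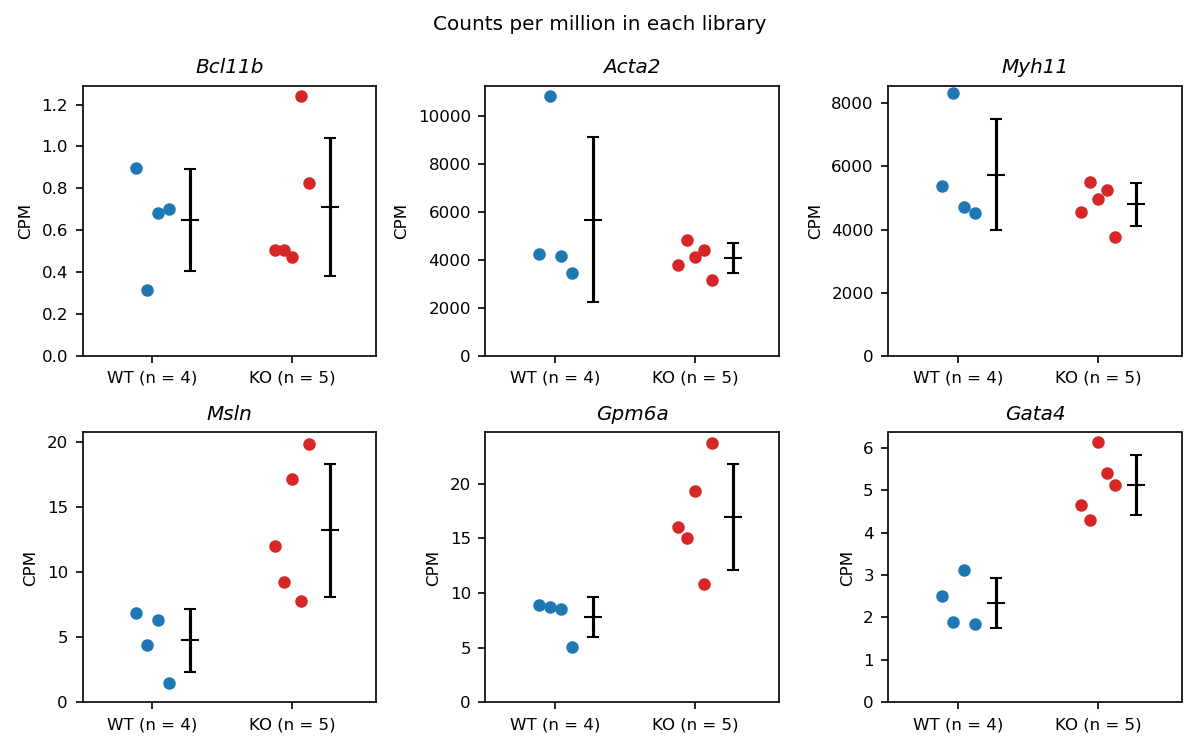
Each point is 1 library, spread sideways for visibility, with normalised CPM on the vertical axis from 0, and the black bars give the mean and SD of 4 WT (blue) and 5 KO (red) libraries. Bcl11b overlapped between groups, Acta2 reached 10831 CPM in WT 2-3 alone, and Gata4 and Gpm6a lay higher in each of the 5 libraries labelled KO, with no gene past the adjusted threshold in edgeR.

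The comparison of KO with WT asked how loss of Bcl11b in vascular smooth muscle alters the aortic transcriptome. None of the 15413 genes tested passed an adjusted p of 0.05 in either direction by edgeR's quasi-likelihood test (smallest adjusted p = 0.501). At an unadjusted p under 0.05 there were 424 genes higher and 288 lower in libraries labelled KO, 712 in all against 771 given by chance. Both the number and the balance depended on the model, as a replicate block gave 1183 genes at this level, 559 higher and 624 lower. With the mesothelial markers as a covariate, chosen after seeing the data, 312 genes were at this level, 127 higher and 185 lower. The mean of these markers did not overlap between groups (centred log2 CPM at most -0.315 in WT and at least -0.079 in KO). The covariate can therefore take out any difference between the groups, and the lower count does not show what those differences depend on. DESeq2 called 14 genes higher and 1 lower, and limma-voom called 0. The groups did not overlap for 221 genes, 1.43% of those tested, against 1.59% by chance. In simulated counts with the same libraries and 15413 genes, 64.8% of 1.5-fold changes, 84.5% of 2-fold changes and 99.4% of 4-fold changes were recovered, with a false share of 6.3%. Genes were drawn independently there and many were changed at once. A mean of 0 lists beside the changed one were called, against a median of 14 lists in other splits of the real libraries. In the real libraries genes vary together, so these percentages may be too high for them.

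The genes with the smallest p-values are given as values, not as changed. Among those higher in libraries labelled KO were Gata4, a GATA-family transcription factor, at 2.34 ± 0.596 CPM in WT (SD, n = 4) and 5.13 ± 0.71 CPM in KO (SD, n = 5), a 2.25-fold ratio. Gpm6a, which encodes a membrane glycoprotein, stood at 7.81 ± 1.85 CPM in WT and 17.0 ± 4.85 CPM in KO, a 2.18-fold ratio. Aldh1a2, the main retinoic acid-producing dehydrogenase of the embryo, had a log2 fold change of 1.42 with a standard error of 0.28. The log2 fold changes of Gal3st2, a galactose sulfotransferase, and Ano4, an anoctamin, were 1.32 and 1.74. All of these had an adjusted p of 0.501 or 0.508 in edgeR. DESeq2 called these 5 genes, together with Bnc1, Sytl5, Upk1b, Krt19, Krt7, Haus8, Rpl7, Rpl23a and Scarna2, which were listed after their values were seen. Gpm6a, Upk1b and Krt19 are members of the fixed list of mesothelial markers described below, so their values are not separate from the result of that list. Whether the other genes, Gata4, Aldh1a2, Bnc1 and Krt7 among them, vary with that list was not tested. They are therefore not taken as separate from it either. Among the lower genes, Crispld1 was at 55.9 ± 5.80 CPM in WT and 43.1 ± 0.471 CPM in KO, and it was the gene that DESeq2 called lower. Btc, which encodes the growth factor betacellulin, had a log2 fold change of -0.29, Rapgefl1 of -0.60, Aatk of -0.36 and Rab39b of -0.50, with adjusted p-values of 0.508 in edgeR.

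Marker genes of mesothelium, the cell layer that covers the pleura and pericardium, were called higher as a group in libraries labelled KO by camera with a preset correlation only. The 12 tested members had a median log2 fold change of 1.49, 11 of them lay above 0, and 10 passed when adjusted over the list alone, against 0 over all genes tested (edgeR). Camera with a preset correlation gave an adjusted p of 7.29e-15 over 45 lists, while the adjusted p was 0.671 with an estimated correlation and 0.435 by fry. The list mean was 1.51 ± 0.492 log2 CPM in WT (SD, n = 4) and 2.70 ± 0.528 log2 CPM in KO (SD, n = 5), with an exact permutation p of 0.0159 and an adjusted p of 0.714 over the lists. With a smallest possible p of 0.00794, 1 list alone could not have passed this adjustment over 45 lists. Msln, which encodes mesothelin, was at 4.76 ± 2.44 CPM in WT and 13.2 ± 5.13 CPM in KO. Upk3b was at 7.19 ± 3.47 CPM in WT and 21.3 ± 10.03 CPM in KO, and Krt19, a keratin, had a log2 fold change of 1.98. Cdh3, a cadherin with the highest mean of the list over all libraries, was at 20.4 ± 2.96 CPM in WT and 19.8 ± 3.32 CPM in KO. Rspo1, a secreted enhancer of Wnt signalling that the Wnt list also holds, had a log2 fold change of 1.05.

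The smooth muscle contractile apparatus, the main gene programme of the aortic media, was not called. Its 30 members had a median log2 fold change of -0.04 and 21 lay below 0 (camera adjusted p = 0.259). Myh11, the smooth muscle myosin heavy chain, was at 5735 ± 1758 CPM in WT and 4806 ± 682 CPM in KO, and Acta2, smooth muscle actin, at 5684 ± 3449 CPM and 4070 ± 627 CPM. WT 2-3 held 10831 CPM of Acta2, 2.73 times the mean of the other WT libraries. The 95% interval of the Myh11 log2 fold change ran from -0.66 to 0.15. Without WT 2-3 that log2 fold change moved from -0.26 to -0.02, and that of Acta2 turned from -0.48 to 0.04.

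Camera with a preset correlation called 9 lists higher and 6 lower in libraries labelled KO, and no list held a gene past the threshold over all genes tested. None of these calls remained with an estimated correlation, where the smallest adjusted p was 0.671, and fry called 0 lists. Without WT replicate 1, 4 lists were called higher, and without KO replicate 1 or KO replicate 5, 3 were called lower. Ribosomal protein genes had a median log2 fold change of 0.16, with 28 of 31 members above 0 (preset adjusted p = 8.89e-12, adjusted p = 0.832 with an estimated correlation). Rpl7, at 188 ± 7.28 CPM in WT and 225 ± 13.8 CPM in KO, passed when adjusted over the list alone. The ribosomal RNA gene Rn45s held 1.82% and 1.77% of the counts in WT replicates 2 and 3 and at most 1.11% in any other library. Macrophage and monocyte markers had a median of 0.22, with 16 of 18 above 0 (adjusted p = 0.832 with an estimated correlation). The macrophage gene Lyz2 was at 103 ± 22.9 CPM and 102 ± 15.6 CPM in WT and KO, and F13a1 at 65.5 ± 20.1 CPM and 77.7 ± 6.73 CPM, a log2 fold change of 0.26 that moved to 0.49 without WT replicate 4 and 0.17 without WT replicate 5. Interferon-stimulated genes had a median of 0.16 with 20 of 24 above 0, immediate early genes 0.17 with 19 of 21, cell cycle genes 0.11 with 18 of 24, p53 targets and senescence genes 0.06 with 14 of 17, and complement genes 0.11 with 15 of 19. With an estimated correlation their adjusted p-values were 0.832, 0.832, 0.832, 0.832 and 0.879. Cholesterol and fatty acid synthesis genes had a median of 0.17 with 23 of 25 above 0 (adjusted p = 0.879 with an estimated correlation). KO replicate 3 held 1888 CPM of Fasn, the fatty acid synthase, against 813 ± 172 CPM in the other KO libraries, and without it this list was no longer called at a median of -0.01. When each of the 9 libraries was left out in turn, the mesothelial and ribosomal protein calls held each time. The macrophage call was lost without WT replicate 1 or 5 (camera adjusted p up to 0.109) and the interferon call without WT replicate 1 or KO replicate 4 (up to 0.0644). The immediate early call was lost without WT replicate 1, KO replicate 1 or KO replicate 4 (up to 0.380), the cell cycle call without WT replicate 1, WT 2-3 or KO replicate 1 (up to 0.240) and the p53 call without WT replicate 1, WT replicate 5 or KO replicate 4 (up to 0.264). The cholesterol call was lost without WT replicate 5 or KO replicate 3 (up to 0.777), and the complement call was lost without 6 of the 9 libraries, namely WT replicates 1 and 5 and KO replicates 1, 3, 4 and 5 (up to 0.867).

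Of the 6 lower lists, calcium handling and ion channels of smooth muscle had a median log2 fold change of -0.09 with 21 of 28 members below 0, and pericyte markers -0.18 with 8 of 9 below 0. With an estimated correlation both adjusted p-values were 0.832. Atp2a2, the calcium pump of the sarcoplasmic reticulum, was at 1089 ± 144 CPM in WT and 958 ± 145 CPM in KO, and the pericyte and smooth muscle gene Rgs5 at 3052 ± 832 CPM and 2513 ± 425 CPM. Without WT 2-3 the log2 fold change moved from -0.28 to -0.07 for Rgs5 and from -0.19 to -0.09 for Atp2a2, which was at -0.11 without KO replicate 5. Fibrillar and basement membrane collagens had a median of -0.12 with 16 of 22 below 0, and the nitric oxide-cGMP-PKG pathway -0.08 with 12 of 14 below 0. Col3a1 was at 1802 ± 530 CPM in WT and 1603 ± 205 CPM in KO, and its log2 fold change of -0.17 turned to 0.06 without WT 2-3 and was -0.28 without WT replicate 5. Brown adipose markers had a median of -0.22 with 13 of 15 below 0, and fatty acid oxidation genes -0.06 with 15 of 20 below 0. With an estimated correlation the adjusted p was 0.879 for the collagens, 0.832 for the nitric oxide pathway, 0.879 for brown adipose markers and 0.879 for fatty acid oxidation genes. With the mesothelial markers as a covariate, a setting chosen after seeing the data, 5 of the 6 lower calls were lost, all but that of the collagens, and so were 7 of the 9 higher calls. As this covariate did not overlap between groups, it can take out any group difference, and these losses do not show a link to mesothelium. With that covariate calcium handling had a median of 0.01 (camera adjusted p = 0.729). Its call held without each library in turn, though its median then ran from -0.12 to -0.05. The pericyte call was lost without WT 2-3 (camera adjusted p = 0.0679). The collagen call was lost without WT 2-3, WT replicate 4, KO replicate 2 or KO replicate 5 (up to 0.608) and the nitric oxide call without WT 2-3, WT replicate 5, KO replicate 1 or KO replicate 5 (up to 0.304). The brown adipose call was lost without WT replicates 1 or 5 or KO replicates 1 or 4 (up to 0.916), with a median of 0.07 without WT replicate 1, and the fatty acid oxidation call without WT replicates 1 or 5 or KO replicates 1, 4 or 5 (up to 0.782).

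**Figure D2:**
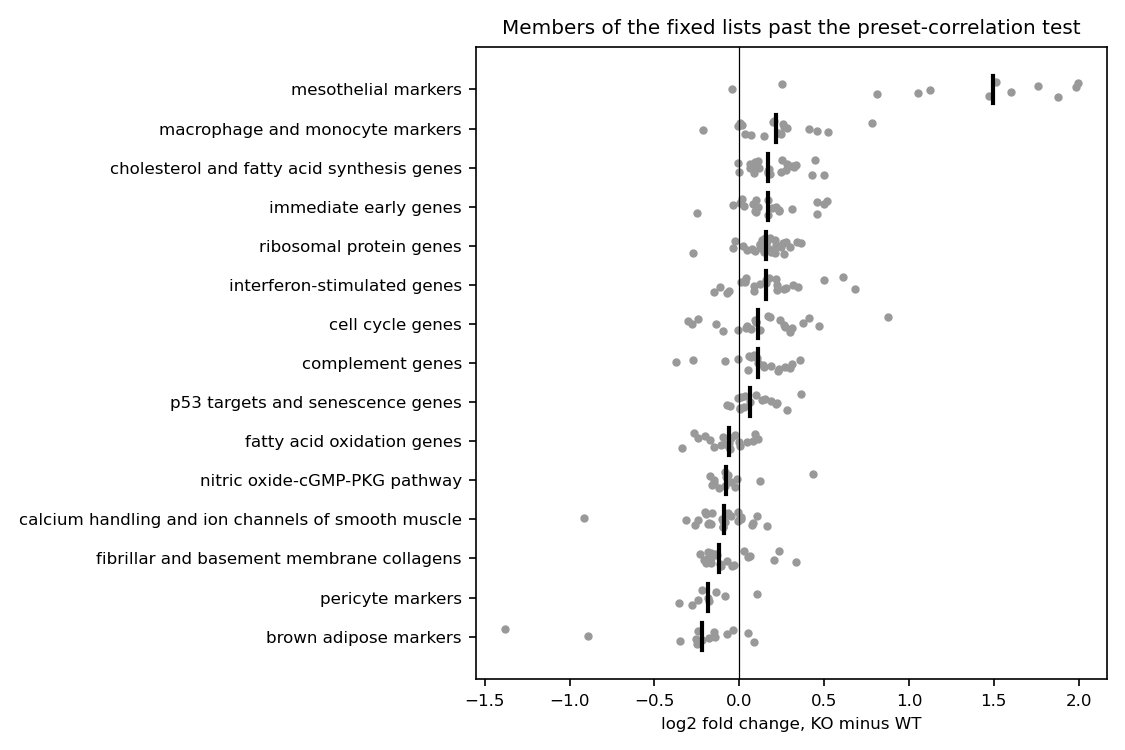
Each grey point is the log2 fold change, KO minus WT, of 1 tested member of a fixed list, and black bars mark list medians, for the 15 lists called by camera with a preset correlation. The mesothelial median of 1.49 stood apart from the others, which ran from -0.22 to 0.22, and none of the 15 calls remained with an estimated correlation.

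The other 30 lists were not called by camera. Among markers of other cell types, the median log2 fold change was 0.19 for endothelial cells, 0.01 for adventitial fibroblasts, -0.02 for adipocytes, -0.03 for Schwann cells and neurons, 0.10 for skeletal muscle, 0.13 for cardiac muscle, -0.01 for T cells, -0.26 for B cells, 0.31 for neutrophils and mast cells and -0.21 for erythroid cells. Cardiac Tnnt2, a troponin, was at 5.63 ± 0.876 CPM in WT and 9.37 ± 2.12 CPM in KO, and it passed with Myl7 and Ankrd1 when adjusted over the list alone. Adjustment over a list alone, here and below, does not correct across the 45 lists, of which 7 held such members. Over all genes tested, 0 lists held a member past the threshold, so these genes are not taken as changed. The cardiac list mean overlapped between groups, at -0.393 to 0.360 in WT and -0.487 to 0.678 in KO (centred log2 CPM). Its member Myh6 ran from 2.47 CPM in KO replicate 1 to 78.3 CPM in KO replicate 3. Among signalling lists the medians were -0.04 for vasoactive receptors, 0.02 for Notch, -0.02 for Wnt, -0.03 for TGF-beta and BMP, -0.03 for calcineurin-NFAT and 0.01 for actin and SRF targets. Rgs2, a regulator of G protein signalling, was at 30.0 ± 3.28 CPM in WT and 23.6 ± 2.09 CPM in KO and passed when adjusted over the list alone. Matrix lists had medians of -0.04 for elastic fibre genes, -0.05 for matrix proteases, -0.03 for proteoglycans and -0.07 for osteochondrogenic genes. In the osteochondrogenic list Bmp4, at 28.6 ± 4.20 CPM in WT and 41.7 ± 7.47 CPM in KO, passed when adjusted over the list alone. The remaining medians were 0.20 for inflammatory mediators, 0.02 for respiratory chain genes, -0.03 for glycolysis, 0.01 for heat shock and unfolded protein response genes, 0.06 for glucocorticoid-responsive genes, 0.01 for clock genes, -0.09 for replication-dependent histones, -0.06 for positional genes and -0.05 for the relatives and partners of BCL11B. Median and mean differed in sign for skeletal muscle, adipocyte, Wnt, proteoglycan, elastic fibre, calcineurin-NFAT and TGF-beta and BMP lists, and camera put the clock and skeletal muscle lists lower and the Wnt list higher, against their medians.

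As a check of the dissections, the leading markers of other tissues were read in each sample. The skeletal muscle actin Acta1 ranged from 146 to 370 CPM, the adipocyte gene Plin4 from 2579 to 4013 CPM and the erythroid gene Alas2 from 13.4 to 41.9 CPM. Other markers, read after their values were seen, varied more. Cardiac Myh6 ranged from 2.47 to 78.3 CPM and Ttn from 41.7 to 279 CPM, both from KO replicate 1 to KO replicate 3. Ucp1 of brown fat ranged from 6.66 CPM in KO replicate 4 to 60.1 CPM in WT replicate 1. The mesothelial gene Upk3b ranged from 2.42 to 10.1 CPM in WT and from 11.6 to 36.6 CPM in KO, with no overlap. Xist was between 3.25 and 5.67 CPM in every library, and the 46 genes on the Y chromosome had 0 counts in all libraries. The labels give no sex, and how reads were assigned to these genes is not given, so sex was not read from these values.

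Libraries labelled WT 2-3 and KO replicate 3 stood apart in clock genes. Arntl, a core activator of the circadian clock, was at 37.6 CPM in WT 2-3 and 60.3 CPM in KO replicate 3 against 6.03 ± 1.52 CPM in the other 7 libraries. Dbp, an output gene of the opposite phase, was at 64.1 and 5.27 CPM against 123 ± 16.7 CPM. With both libraries left out, 0 genes passed and 564 had an unadjusted p under 0.05 in edgeR. Camera with a preset correlation then no longer called the nitric oxide, collagen, interferon, pericyte and cholesterol lists.

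**Figure D3:**
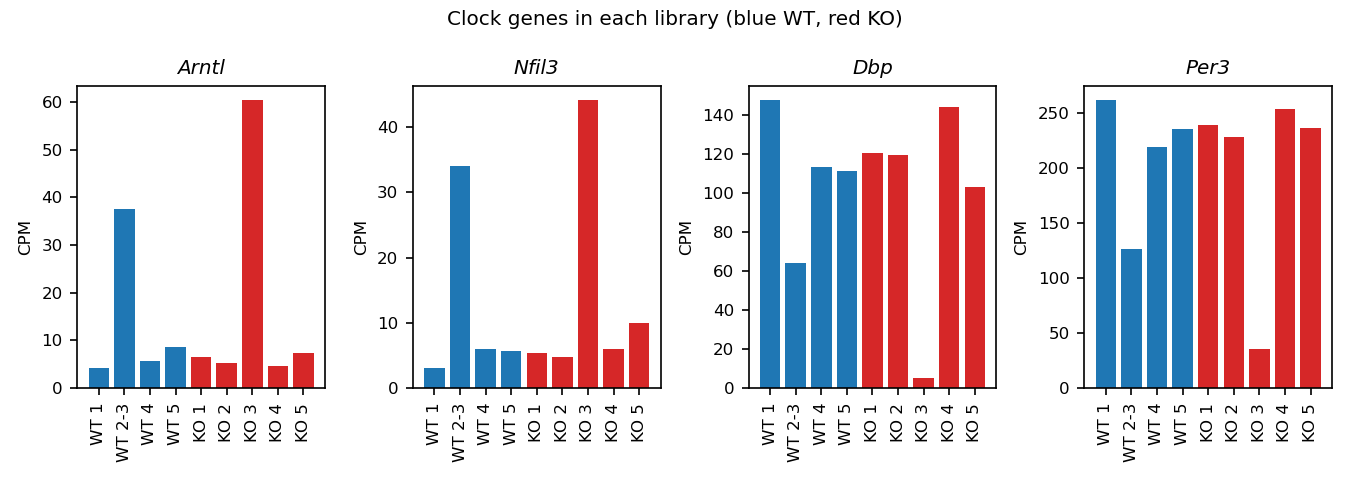
Bars give normalised CPM, from 0, of 4 clock genes in each of the 9 libraries, 4 WT in blue and 5 KO in red. Arntl and Nfil3 were higher and Dbp and Per3 lower in WT 2-3 and KO replicate 3 than in the other 7 libraries.

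As no gene was called, genes within 20 Mb of Bcl11b were compared with the rest at an unadjusted p. Of 168 tested genes in this window 11 had an unadjusted p under 0.05, or 6.55%, against 4.65% of the genes elsewhere (Fisher's exact test, two-sided, p = 0.265).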

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

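All tests of explanations in this part except that of GC content and length were chosen after the result was seen. The criteria for the counts over other splits were also corrected in wording afterwards. Of 114 groups of values checked for an outlying library 9 stood out, and chance alone gives about 1 in 20, or 5.70. Each value below is the distance of the library from the median of the others in its group on the log2 scale. WT 2-3 was 0.32 higher in actin and SRF target genes and 0.68 higher in histone genes. WT replicate 4 was 0.40 higher in interferon-stimulated genes, WT replicate 1 was 0.73 higher in Gal3st2 and WT replicate 5 was at -0.78 in Gpm6a. KO replicate 2 was at -0.32 in complement genes. KO replicate 3 was 0.77 higher in cholesterol and fatty acid synthesis genes, and was at -0.87 in clock genes and at -0.25 in positional genes.

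WT replicates 2 and 3 matched more closely than counting noise allows. A chi-square per degree of freedom of 0.769 fits 1 library deposited under 2 names, and the other 44 pairs began at 3.29. Preparations made separately from 1 aorta would raise it above 1, and it lay 20.3 standard deviations below, at -20.3. No biological explanation was tested, and the cause of a value below 1 stays open. Whether both columns hold some of the same reads was not tested. If they do, the summed counts of WT 2-3 are too high as a measure of depth and its CPM for a given count is too low.

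The clock genes of WT 2-3 and KO replicate 3 were out of phase with the other 7 libraries. Bias by GC content or length is argued against, since removing their trend left at least 100.1% of the gap between phases. All 15 of 15 clock genes lay outside the range of the other libraries in the direction of their phase in both, which is consistent with collection at another time of day, a hypothesis. If WT 2-3 mixed RNA of both phases, each gene should imply the same share, and the implied shares ran from 0.406 to 1.01. That range of 0.601 passed the limit of 0.5 set for it, but by less than its error of 0.386, a term added after the range had been seen, so mixing cannot be told apart from an intermediate time.

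Mesothelial markers were called higher in libraries labelled KO with a preset correlation, but not with an estimated one (adjusted p = 0.671) or by fry (adjusted p = 0.435), and 0 members passed over all genes tested. A lower share of smooth muscle RNA would raise the markers of other cell types alike, yet the highest median among 4 of those lists was 0.19, for endothelial cells, against 1.49. Carried-along mesothelial tissue is a candidate explanation. The markers varied together within groups, with a mean correlation of 0.578 against 0.155 at the 95th percentile of matched lists. The other fixed lists ran from 0.0127 to 0.753 on this measure, and histone genes, which mark no tissue, had 0.733. Markers of 1 cell type would vary together under either cause, so this value does not part carried-along tissue from an effect of the genotype. Msln and Upk3b, among the most abundant, had means of 13.2 and 21.3 CPM in KO. Cdh3, with the highest mean of the list over all libraries, was not higher, at 20.4 CPM in WT and 19.8 CPM in KO. An effect of the genotype stays open as well, with an exact permutation p of 0.0159 for the list mean and 0.714 after adjustment.

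Chance could not be excluded for the group comparison. Of 100 splits of the 9 libraries, the real one included, 56 gave at least the 712 genes with an unadjusted p under 0.05, with 1822 in the highest other split, which parted WT 2-3, WT replicate 4 and KO replicates 2 and 3 from the rest. The next, with 1610, parted replicates 1 and 5 of both groups from the rest. It differs from the highest only in the side of KO replicate 4. Total counts were 15311118 to 17459085 in replicates 1 and 5 of both groups. They were 10156566 to 12744614 in WT replicate 4 and KO replicates 2 to 4. WT 2-3, with 39351775, breaks this order of depth. The splits that followed, with 1521 and 1491 genes, mixed deeper and shallower libraries on each side. What underlies these splits, a processing batch included, was not tested. For the 15 lists called, 46 splits gave as many, with 28 in the highest other. For genes past the adjusted threshold the real count was 0, so all 100 splits give at least as many and the count decides nothing, with 5 in the highest other.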

How the results depend on the processing

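The settings marked as added after seeing the data were the 10 columns as separate libraries, the second replicate block, leaving out WT 2-3 with KO replicate 3, the mesothelial and Arntl covariates, and TMM-normalised CPM for the T cell correlation. The count of 0 genes past the threshold held in each setting except DESeq2, which called 14 genes higher and 1 lower in libraries labelled KO, and the cause was not tested. Smallest adjusted p-values elsewhere ran from 0.134 to 0.9997. With 10 columns edgeR called 0 genes, and 1110 had an unadjusted p under 0.05. Lists called higher ran from 4 to 13 and lists called lower from 3 to 7 when leaving out 1 replicate at a time, with 4 higher without WT replicate 1 and 3 lower without KO replicate 1 or KO replicate 5. With the mesothelial covariate, which takes out the mesothelial list by construction, 12 of the 15 list calls were lost. Its values did not overlap between groups, so it can also take out other group differences, real ones included. Of the 4 lists then called higher, 2 were among the 9, ribosomal protein and immediate early genes. The collagens alone of the 6 lower lists were called again, and the complement list was called lower, with a median of -0.15. An estimated correlation and fry each left 0 lists higher and 0 lower. The Bcl11b log2 fold change of 0.21 turned to -0.046 with 1 surrogate variable and -0.029 with WT 2-3 and KO replicate 3 left out, and ran from -0.13 to 0.45 when leaving out 1 replicate, with -0.13 without WT 2-3 and -0.04 without KO replicate 4. The cause was not tested. Settings that filtered Bcl11b out give no value, and the test of called genes near Bcl11b gave none because no gene was called. The mesothelial list was called in 27 of 28 settings, the ribosomal protein list in 28 and the complement list in 14. For 99 named genes 2752 values moved by less than the spread between libraries and 20 by more. That spread was the larger within-group SD of log2 CPM, so a log2 fold change that turned can count as moved by less. Acta2, for example, turned from -0.48 to 0.04 without WT 2-3, within that spread, so these counts do not show that the values are stable. Same-number correlations were 0.0405 for number 1, 0.0900 for number 4 and 0.170 for number 5, and for WT 2-3 they were -0.000899 with KO replicate 2 and 0.189 with KO replicate 3, the highest of any pair. With either number not every pair exceeded 0.1, so the numbers were not taken to pair the samples. As a hint from the data, WT 2-3, WT replicate 4 and WT replicate 5 correlated best with KO replicates 3, 4 and 5, but WT replicate 1 with KO replicate 2. WT 2-3 and KO replicate 3 are also the libraries apart in clock genes. The replicate block gave 0 genes higher, 0 lower, 6 lists higher, 6 lists lower, a Bcl11b log2 fold change of 0.19 and 1183 genes with an unadjusted p under 0.05, 559 higher and 624 lower. With the joined library as number 3 the replicate block gave 0 genes, 9 lists higher, 7 lists lower and 1411 genes at that level, 662 higher and 749 lower, against 424 higher and 288 lower without a block. Depth limits low genes most, as Bcl11b had at most 14 counts in a library.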

Other observations

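All tests in this part were chosen after the result was seen, and the one without Thy1 after that with it. WT 2-3 differed from the other WT libraries in several abundant transcripts, with Malat1 at 25625 CPM against 11836 ± 1213 CPM and Tg, the thyroglobulin gene, at 45.4 CPM against 5.77 ± 0.939 CPM (SD, n = 3). Hspa1a, an inducible heat shock gene, was at 334 CPM against 96.95 ± 27.04 CPM. KO replicate 3 held 17.2 CPM of Mb, the myoglobin gene, against 1.12 ± 0.779 CPM in the other KO libraries (SD, n = 4), and 14.4 CPM of Spp1, the osteopontin gene, against 1.47 ± 0.744 CPM. Cardiac Myh6 was also highest in KO replicate 3, at 78.3 CPM against 17.8 ± 17.6 CPM in the other KO libraries. These genes were chosen after their values were seen.

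A hypothesis was that the few Bcl11b reads may come from T cells in the tissue. Across the 9 libraries Bcl11b CPM, here of the total counts without TMM factors, had a Pearson r of 0.491 with the summed CPM of the T cell markers (exact permutation p = 0.177, adjusted p = 0.236 over the 4 relations computed, 2 marker sums on 2 scales) and a Spearman rho of 0.55 (exact permutation p = 0.133, adjusted p = 0.177). Without the 2 libraries farthest from the median of the T cell sum r was 0.619. Thy1, which fibroblasts also make, held 42.7% to 65.7% of that sum. Over the markers other than Thy1, r was 0.880 (exact permutation p = 0.00165, adjusted p = 0.00661) and rho 0.80 (exact permutation p = 0.0138, adjusted p = 0.0428), and r was 0.788 without the 2 libraries farthest from the median. With TMM-normalised CPM r was 0.354 with Thy1 (exact permutation p = 0.351, adjusted p = 0.351) and 0.802 without it (exact permutation p = 0.0110, adjusted p = 0.0220), and rho was 0.317 (exact permutation p = 0.410, adjusted p = 0.410) and 0.767 (exact permutation p = 0.0214, adjusted p = 0.0428). The relation thus depends on leaving out Thy1, a choice made after the first value was seen, and rests on at most 14 Bcl11b counts in a library, so a T cell source stays a hypothesis.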
